A study of Pimephales promelas with 291 samples.

How the data were processed

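Gene expression was measured in RNA from whole fathead minnow larvae (Pimephales promelas, a small freshwater fish used in toxicity testing) on single-colour (Cy3) Agilent oligonucleotide microarrays. Each array held 62372 spots, 61053 of them non-control. The non-control spots covered 49849 different probes, of which 41517 had 1 spot, 7973 had 2 spots and 359 had 10 spots. Larvae were 48 h old at the start, in vessels of 10, and were exposed for 48 h to a pyrethroid insecticide or to control water, in 7 exposure runs, with 3 aquaria per treatment per the labels.

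The deposited scanner output gave, for each spot, a processed signal in units of intensity, which the authors obtained with Agilent Feature Extraction software, together with the median foreground and background intensity and the outlier flags. The authors also deposited a table of 1 value per probe and array, in log2 units after quantile normalization over all arrays. That table held 49894 lines, of which 45 carried no values. Every column had the same median, 7.98, and the values of an array ranked probes almost exactly as the median signal did, with a lowest Spearman's rho of 1.00 to 2 decimals over the arrays.

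The main values were computed from the processed signal. Outlier spots marked by the scanner software, 0.241% of non-control spots, were left out, which left 0.0116% of probe values missing. The log2 signal of each spot was taken relative to the 75th percentile of the non-control spots of its array, and the spots of a probe were averaged. A probe was tested if its signal was well above background on at least 0.5 of the arrays of at least 1 group, which kept 45922 probes in runs 1 to 3 and 43680 in runs 4 to 7.

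Groups followed the labels: exposure run, pyrethroid and nominal concentration, 27 groups in all. The controls of a run were 1 group, since the labels do not separate solvent from water controls. Runs 1 to 3 were fitted together with run as a block. Runs 4 to 7 were fitted together with each exposed group compared with the control of its own run. Linear models with moderated statistics were fitted with limma 3.58.1 in R 4.3.3, all tests were two-sided, and a probe was called when its Benjamini-Hochberg adjusted p was under 0.05. Counts of probes called, the direction of change and the fold change relative to the control of the same runs were reported. The standard error of each log2 fold change came from the same fit.

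A pooled signature was scored in runs that had no part in choosing it. It took the 25 probes with the largest and the 25 with the smallest moderated statistic for the mean of the 4 pyrethroids in the training runs, and the score of an array was the mean of the former minus the mean of the latter. Runs 1, 2 and 3 were each scored with the other two as training, and runs 4 to 7 with all 3. Exposed and control arrays were compared by the area under the receiver operating characteristic curve (AUC), the chance that an exposed array scored above a control array, with an exact two-sided Mann-Whitney test adjusted over the 7 runs. A bifenthrin profile score was added after the data were examined. It projected each array on the bifenthrin fold changes of the training runs, over the probes called in them, so that 0 was the mean of the training controls and 1 the mean of the training bifenthrin arrays. Its differences carried 95% bootstrap intervals from 10000 resamples and an exact two-sided Mann-Whitney test adjusted over 20 comparisons.

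The groups, the comparisons, the tests, the filter, the scaling and most alternatives were fixed before the data were examined. Alternatives were normexp background correction (offset 50) of the median signal with quantile normalization, quantile normalization of the processed signal, the authors' table, no filter on dim probes, a filter requiring signal well above background on 0.9 of all arrays, outlier spots kept, slide as a fixed or random block, position on the slide as covariates, array weights, the replicate number as a block, run as the unit, each run left out in turn, each run fitted alone, and 10 or 100 probes each way in the signature. Normexp correction used the median signal because the files held no mean signal. After the data were examined, scan day as a block, the removal of 3 arrays whose median correlation with the arrays of their group was under 0.9, the mean of the 3 pyrethroids other than bifenthrin, and a signature trained without bifenthrin were added.

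The probes carry sequence identifiers, and 0 of the 49849 matched the reference gene table of 64593 entries. Comparisons were therefore made on probes. Gene lists, gene set tests and the choice of 1 probe per gene were not run. The rule for named genes, set before the data were examined, allowed 2 probes with the smallest p to be given by identifier where no gene had a name; 2 probes with lower signal were added after their values were seen. Recovery of known changes was tested on simulated data, with 50 probes changed at each of 4 sizes among arrays of the real size and spread. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.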

Results

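The data were gene expression profiles of whole fathead minnow larvae after 48 h of exposure to bifenthrin, cypermethrin, esfenvalerate or permethrin, pyrethroid insecticides that act on voltage-gated sodium channels of nerve cells. Cypermethrin and esfenvalerate carry an alpha-cyano group, and bifenthrin and permethrin do not. Runs 1, 2 and 3 used concentrations set at 33% of the LC50, the concentration lethal to 50% of larvae. These were 0.15 µg/L bifenthrin (11, 10 and 11 arrays in the 3 runs), 0.2 µg/L cypermethrin (12, 8 and 13), 0.15 µg/L esfenvalerate (8, 9 and 12) and 0.4 µg/L permethrin (10, 10 and 11), with 20, 18 and 20 control arrays. Runs 4 to 7 each tested 1 pyrethroid at 2 concentrations. Run 4 had 8 controls, 11 arrays at 0.15 and 10 at 0.3 µg/L bifenthrin, and run 5 had 7 controls, 10 arrays at 0.5 and 9 at 1 µg/L cypermethrin. Run 6 had 9 controls, 9 arrays at 0.5 and 3 at 1 µg/L esfenvalerate, and run 7 had 10 controls and 11 arrays each at 1.56 and 3.13 µg/L permethrin.

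The median array had signal well above background on 84.6% of its spots, with a range from 37.9% to 99.2%. The 75th percentile of intensity had a median of 797 over the arrays and ran from 145 to 2317. Spike-in RNA followed its known amounts (r² over 0.9) on 59 of the 61 arrays of run 1 and on every array of runs 4 to 7. It did so on 2 of the 55 arrays of run 2 and 2 of the 67 of run 3. On the remaining arrays the scanner software reported a slope and r² of exactly 0, which does not tell whether spike-in RNA was present there. The number of arrays limits the precision. Each treatment had 3 aquaria, fewer than its arrays in most groups, so that some arrays of a group shared an aquarium. The labels do not say which, and p-values based on the spread between arrays can therefore be too small.

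The study asked whether a set of genes marks exposure to pyrethroids as a class. In runs 1 to 3, bifenthrin changed a large part of the measured transcripts and the other pyrethroids changed none that passed the test. With 0.15 µg/L bifenthrin, 15044 of 45922 probes differed from control, 7435 higher and 7609 lower. Most changes were small, with a median size of 0.32 on the log2 scale among the called probes. At least 2-fold changes were seen for 364 probes that rose and 232 that fell, and the extremes were log2 fold changes of 4.35 and -2.44. The median standard error of a log2 fold change was 0.09 over all probes tested.

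The bifenthrin change recurred in each run. Fitted alone, run 1 called 9428 probes (5192 higher, 4236 lower), run 2 called 7515 (4437 higher, 3078 lower) and run 3 called 4661 (1955 higher, 2706 lower). All 3 runs called 1145 probes higher, against 24.1 for independent calls, and 889 lower, against 18.6. Of the 15044 probes called in the joint fit, 13554 (90.1%) had the same sign in each run. Fold changes of different runs correlated across 42082 probes, with r of 0.68 for runs 1 and 2, 0.65 for runs 1 and 3 and 0.53 for runs 2 and 3. Probes are not independent replicates, so the mean r of 0.62 was compared with 100 reshufflings of the treatments within runs, which gave at most 0.35. With slide as a block, 15453 probes were called. With run rather than array as the unit 8883 were called, and without run 1 the count was 9167.

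**Figure D1:**
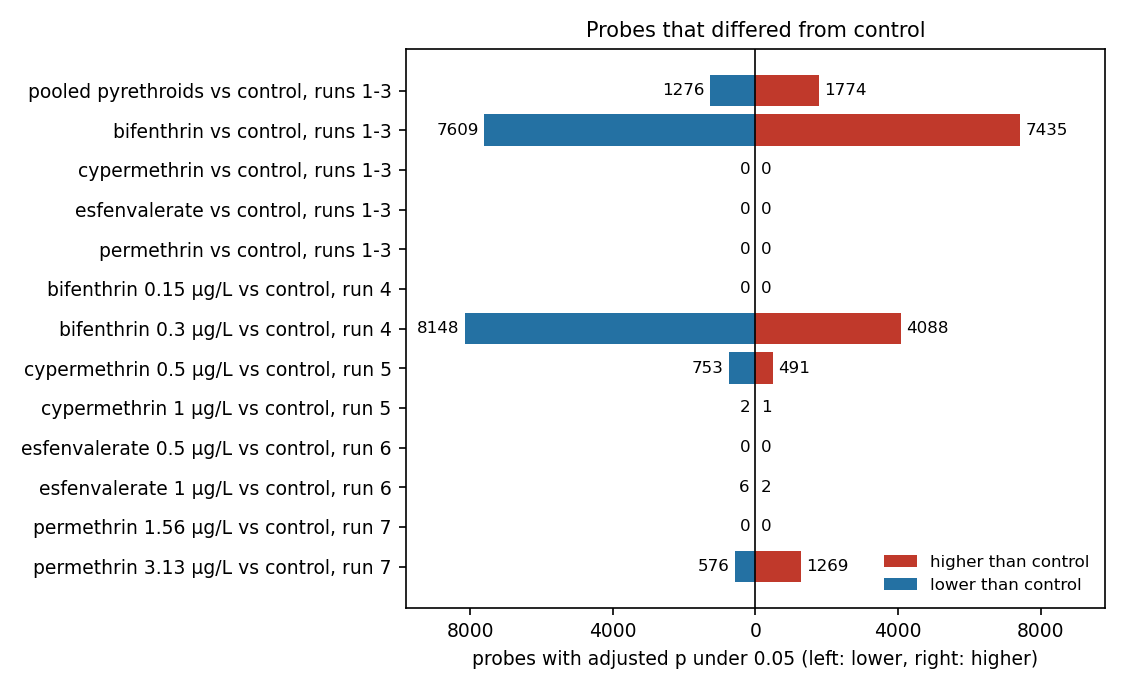
Bars give the number of probes called per comparison with control (horizontal axis, probes with adjusted p under 0.05; red, higher than control; blue, lower than control) for the exposures listed on the vertical axis. Bifenthrin gave 7435 higher and 7609 lower probes in runs 1 to 3, whereas 0.15 µg/L in run 4 gave 0.

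The 2 probes with the smallest p for bifenthrin both rose, and neither has a gene name in the files. UF_Ppr_AF_106628 was 4.08-fold higher (log2 fold change 2.03, SE 0.10, 95% interval 1.84 to 2.22, limma adjusted p 5.58e-46). Its log2 signal relative to the 75th percentile was 1.05 ± 0.36 (SD, n = 20) in run 1 controls and 3.57 ± 0.88 (n = 11) with bifenthrin. The corresponding means were 0.88 ± 0.22 (n = 18) and 2.90 ± 0.48 (n = 10) in run 2. In run 3 controls averaged 0.66 ± 0.20 (n = 20) and bifenthrin arrays were higher by 1.54 (SD 0.46, n = 11). It lay above every control of its run on 10 of 11, 10 of 10 and 11 of 11 bifenthrin arrays. SINGLET_27241 was 4.03-fold higher (log2 fold change 2.01, SE 0.10, adjusted p 1.60e-45). Among probes that fell, UF_Ppr_AF_110062 had a log2 fold change of -1.43 (SE 0.10, adjusted p 5.19e-27) and lay below every control on 11 of 11, 9 of 10 and 9 of 11 arrays. CONTIG6213 had a log2 fold change of -1.96 (SE 0.15, adjusted p 7.20e-26) and lay below every control on 5 of 11, 9 of 10 and 2 of 11 arrays. These last 2 probes were chosen after their values were seen, and all 4 fold changes come from the arrays on which the probes were picked.

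**Figure D2:**
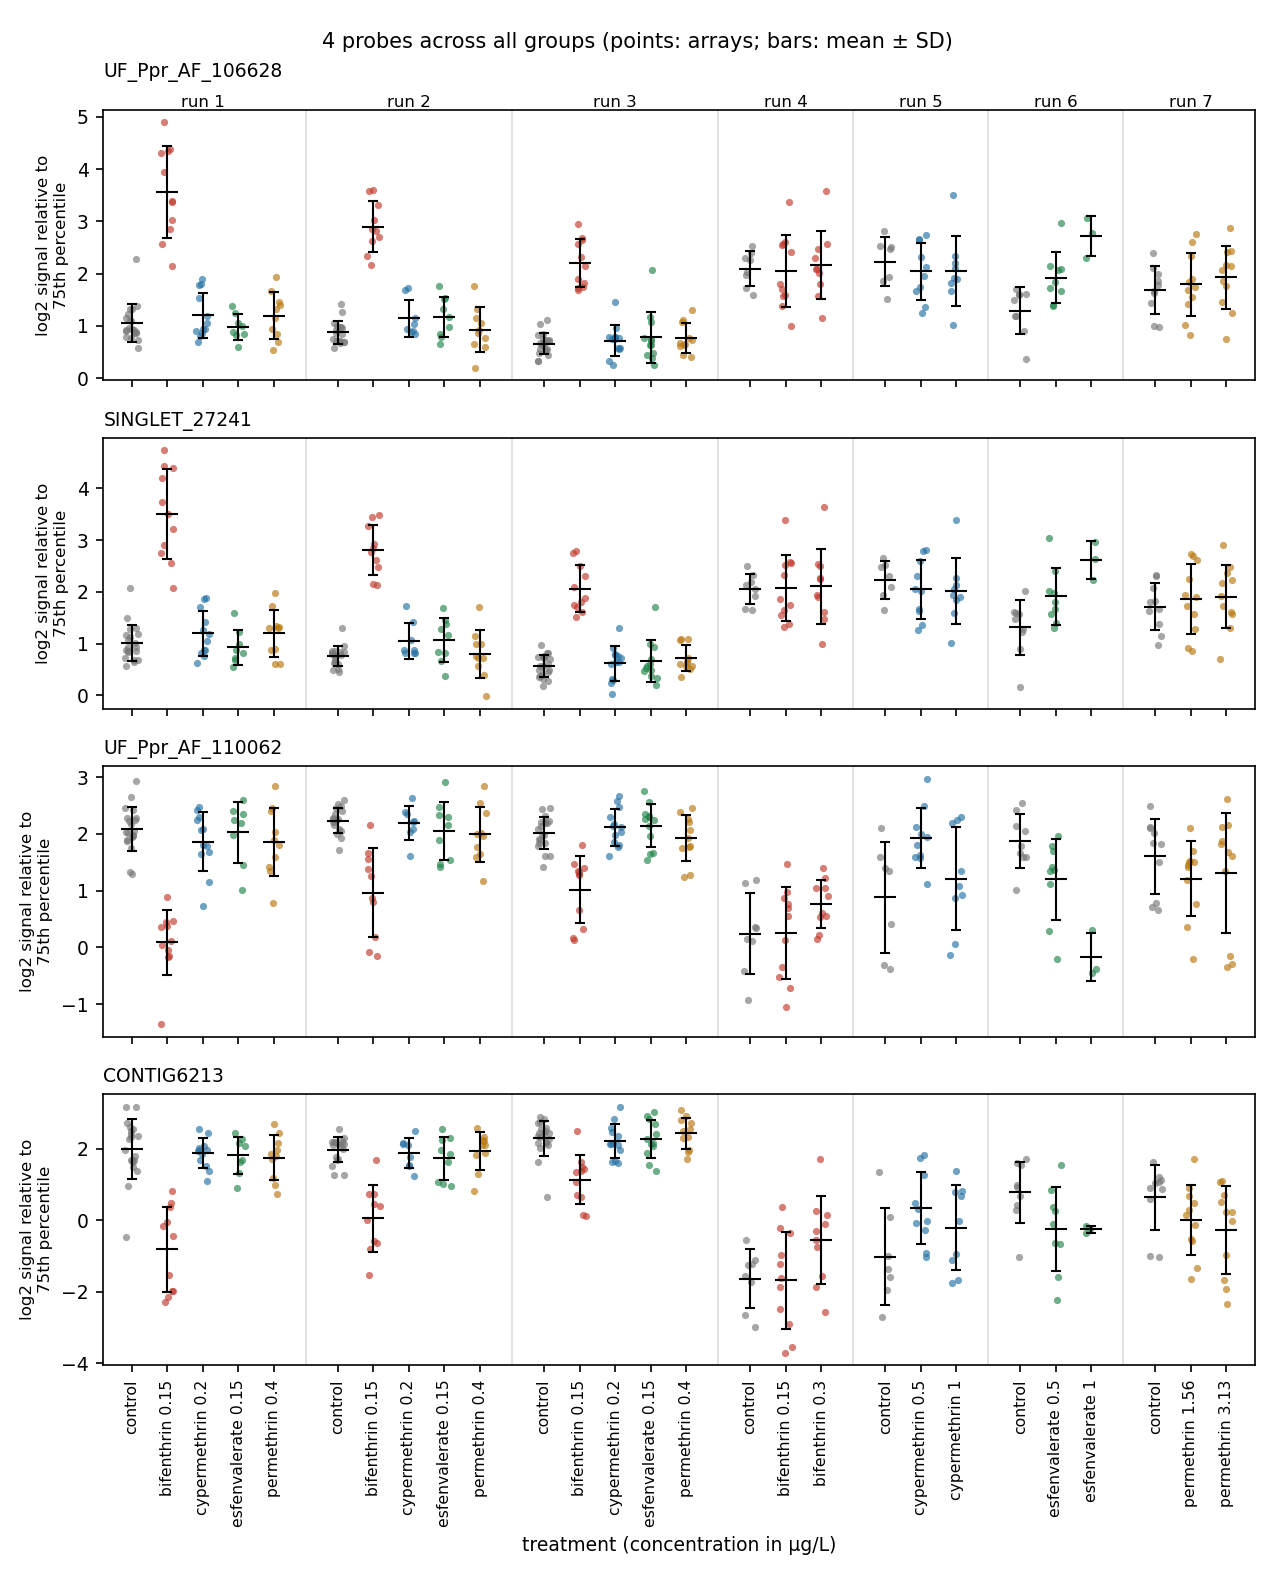
Points are arrays, with mean and SD as bars, for 4 probes (vertical axis, log2 signal relative to the 75th percentile of the array) in every group of the 7 runs (horizontal axis, treatment with concentration in µg/L). UF_Ppr_AF_106628 averaged 3.57 with bifenthrin against 1.05 in controls of run 1, and 2.05 with the same concentration against 2.10 in controls of run 4.

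Cypermethrin, esfenvalerate and permethrin at their equitoxic concentrations called 0 probes each with limma in the joint fit of runs 1 to 3. At an unadjusted p under 0.05 the counts were 1320, 1119 and 1688 of 45922. The smallest adjusted p was 1.00 for each of them. For UF_Ppr_AF_106628 the log2 fold changes were 0.15 with cypermethrin, 0.13 with esfenvalerate and 0.11 with permethrin, and for CONTIG6213 they were -0.11, -0.16 and -0.05. The 95% interval of the fold change lay within 1 log2 unit of 0 for 99.5% of probes with each of these compounds. With arrays taken as independent, changes of 2-fold or more were thus excluded for most probes. Arrays that shared an aquarium can make these intervals too narrow. Fitted run by run, cypermethrin called 0 probes in each run (1724, 2062 and 1746 at an unadjusted p under 0.05). Esfenvalerate called 0, 1 and 0 (1949, 1590 and 1882 unadjusted), and permethrin called 2, 1 and 0 (2978, 2016 and 1346 unadjusted). Fold changes of the same compound in different runs had a mean r of -0.04, -0.07 and -0.05 across probes, and reshuffled treatments gave as high a value in 72, 75 and 82 of 100 cases.

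Bifenthrin and esfenvalerate were compared at the same nominal concentration, 0.15 µg/L, and differed at 10176 probes, 5153 higher and 5023 lower with bifenthrin. Bifenthrin differed from 0.2 µg/L cypermethrin at 11637 probes (5255 higher, 6382 lower) and from 0.4 µg/L permethrin at 10817 (5045 higher, 5772 lower). Without run 1 the esfenvalerate and cypermethrin counts were 6601 and 7505. The other three compounds did not differ from one another at any probe that passed the test. Limma called 0 probes for cypermethrin against esfenvalerate, against permethrin, and for esfenvalerate against permethrin, with 813, 982 and 1209 at an unadjusted p under 0.05. The 95% interval of the difference had a median half-width of 0.21 log2 units and lay within 1 log2 unit of 0 for 99.0%, 99.2% and 99.2% of probes. Any difference among the 4 compounds was called at 10475 probes in the joint fit and at 4068, 4477 and 2071 within runs 1, 2 and 3.

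The mean of the pyrethroids with an alpha-cyano group differed from the mean of those without it at 5619 probes, 2694 higher and 2925 lower. Of these, 5401 (96.1%) were also called for bifenthrin. Permethrin, which shares the absence of the cyano group with bifenthrin, did not differ from either cyano compound at any called probe. Within runs the contrast called 1825, 973 and 258 probes. It called 2299 with run as the unit and between 2326 and 4573 when a run was left out.

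The class comparison, the mean of the 4 pyrethroids against control, called 3050 probes, 1774 higher and 1276 lower. The excess of higher probes depended on the scaling, with 1538 each way after quantile normalization and 1499 higher against 1396 lower in the authors' table. Of the 3050, 3036 (99.5%) were also called for bifenthrin. When bifenthrin was taken out of the mean, a contrast chosen after the data were examined, limma called 0 probes (1730 at an unadjusted p under 0.05). Within runs 1, 2 and 3 the class comparison called 1488, 244 and 194 probes. It called 701 without run 1, 1893 with the replicate number as a block, 4821 with array weights and 1 with run as the unit.

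Run 4 exposed larvae again to 0.15 µg/L bifenthrin, beside 0.3 µg/L. At 0.15 µg/L no probe passed the test. Limma called 0 of 43680 probes (5169 at an unadjusted p under 0.05, smallest adjusted p 0.0604), with a median standard error of 0.20 log2 units. In simulated data at this design 2% of 1.25-fold, 26% of 1.5-fold, 68% of 2-fold and 96% of 4-fold changes were recovered. The simulation changed 50 of 43441 probes at each size, whereas 15044 of 45922 were called in runs 1 to 3. With so many changed probes the adjusted p is less strict, so these rates can understate recovery. How many changes of the size seen in runs 1 to 3 (median 0.32 log2 units) were detectable here is therefore not settled. UF_Ppr_AF_106628 and SINGLET_27241, about 4-fold higher in runs 1 to 3, had log2 fold changes of -0.05 and 0.02. Of 14359 probes called in runs 1 to 3 and measured here, 48.6% had the same sign in run 4, and the fold changes correlated with those of runs 1, 2 and 3 with r of 0.11, -0.16 and 0.15 across probes. The difference between the effects of runs 1 to 3 and of run 4 was itself called at 5345 probes. Under the alternative settings between 0 and 24 probes were called at 0.15 µg/L, 4 of them with slide as a block.

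At 0.3 µg/L bifenthrin changed 12236 probes, 4088 higher and 8148 lower, with a median size of 0.65 log2 units. At least 2-fold changes were seen for 1081 higher and 880 lower probes. The median log2 fold change of all probes was -0.13 in these values and between -0.04 and -0.02 after the quantile scalings. Lower probes stayed in excess after those scalings, at 6256 against 4192 higher with normexp, 6038 against 4620 with quantile normalization and 5990 against 4225 in the authors' table. The 2 concentrations differed from each other at 9322 probes, 3565 higher and 5757 lower at 0.3 µg/L. These changes differed from those of 0.15 µg/L in runs 1 to 3 at 15471 of 46026 probes. Of the earlier calls 43.8% had the same sign, r with runs 1, 2 and 3 was -0.03, -0.15 and 0.10, and UF_Ppr_AF_106628 had a log2 fold change of 0.07. Within the 2 scan days that held most arrays, 938 and 8086 probes were called, and 12641 with slide as a block.

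**Figure D3:**
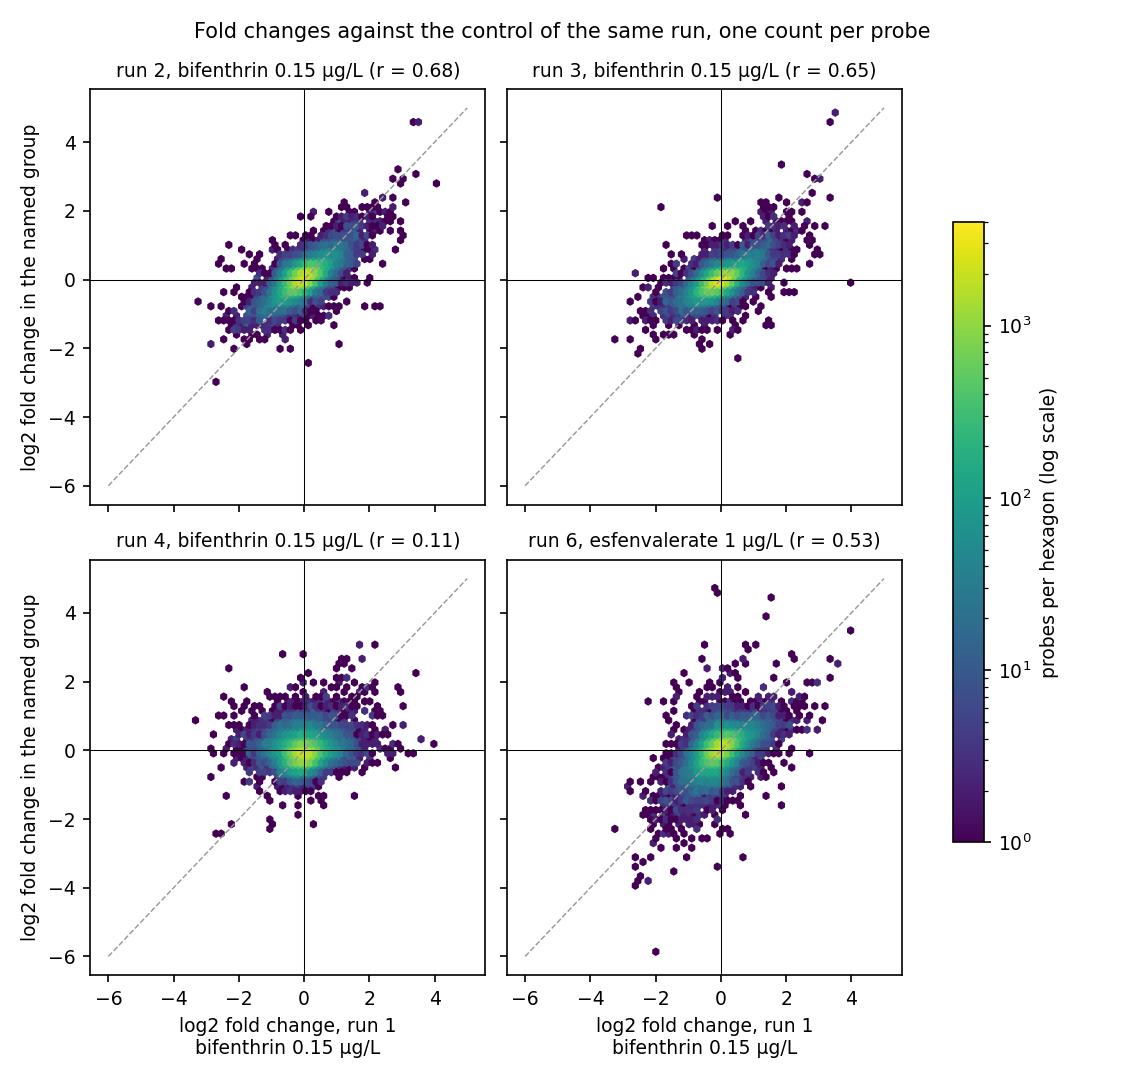
Hexagons count probes by log2 fold change against the control of the same run, with run 1 bifenthrin on the horizontal axis and another group on the vertical axis of each panel (colour, probes per hexagon on a log scale). The fold changes of run 1 correlated with bifenthrin in runs 2 and 3 (r of 0.68 and 0.65) and with 1 µg/L esfenvalerate in run 6 (0.53), but hardly with bifenthrin at the same concentration in run 4 (0.11).

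In run 5 cypermethrin changed more probes at the lower concentration. At 0.5 µg/L 1244 probes were called, 491 higher and 753 lower, with a median size of 0.73 log2 units and with 128 higher and 136 lower by 2-fold or more. At 1 µg/L 3 probes were called, 1 higher and 2 lower, with a median size of 2.26 log2 units. The direct comparison of the concentrations called 2414 probes, 1369 higher and 1045 lower at 1 µg/L, and 5301 with array weights. The 1244 calls became 1545 with slide as a block, 2985 with array weights, and 118 and 178 within the scan days that held most arrays. The 3 calls at 1 µg/L became 0 with slide as a block or with run 5 fitted alone (2499 at an unadjusted p under 0.05 in the joint fit, 3134 in run 5 alone), 9 with array weights, and 25 and 2 within scan days.

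Esfenvalerate in run 6 called few probes, and its fold changes at 1 µg/L shared the direction of the bifenthrin calls of runs 1 to 3 more often than reshuffled treatments did. At 0.5 µg/L limma called 0 probes (3487 at an unadjusted p under 0.05), and at 1 µg/L it called 8, 2 higher and 6 lower, with a median size of 2.22 log2 units. Of the 14359 earlier bifenthrin calls, 83.1% had the same sign at 1 µg/L and 70% at 0.5 µg/L. Treatments reshuffled within run 6, a comparison added after the data were examined, gave a share as high in 0 and 5 of 100 cases. Among the 556 that had changed at least 2-fold, 90.1% had the same sign at 0.5 µg/L and 96.4% at 1 µg/L. Here reshuffling gave a share as high in 1 and 0 of 100 cases. Cypermethrin in run 5 departed the other way, with the same sign for 32.3% and 33.7% of the 14359 and 16.9% and 18.5% of the 556 at 0.5 and 1 µg/L. Reshuffling within run 5 gave a share as low in 5 and 13 of 100 cases for the 14359 and in 5 and 9 for the 556. Permethrin in run 7 at 1.56 and 3.13 µg/L had the same sign for 62.5% and 65.2% of the 14359 and 60.1% and 65.8% of the 556. Reshuffling within run 7 gave a share as high in 14 and 6 of 100 cases and in 31 and 17. The reshufflings were not kept within scan days, and their counts were not adjusted for the number of exposures compared. The esfenvalerate fold changes at 1 µg/L correlated with those of bifenthrin in runs 1, 2 and 3 with r of 0.53, 0.46 and 0.38 across probes, and those at 0.5 µg/L with r of 0.40, 0.20 and 0.38. These r were not compared with reshuffled treatments, and permethrin in run 7 at 1.56 and 3.13 µg/L reached r of 0.34 and 0.42 with bifenthrin in run 2. At 1 µg/L UF_Ppr_AF_106628 had a log2 fold change of 1.42 and UF_Ppr_AF_110062 of -2.04, neither past the test (adjusted p 0.201 and 0.106). The higher concentration had 3 arrays, all from 1 scan day, on which 6 probes were called. Without replicate 2 the count was 0, without replicate 1 it was 14, and run 6 fitted alone called 0 (3268 at an unadjusted p under 0.05). The 2 concentrations differed at 1 probe.

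Permethrin in run 7 called probes at the higher concentration and not at the lower one. At 3.13 µg/L 1845 probes were called, 1269 higher and 576 lower, with a median size of 0.64 log2 units and with 39 higher and 90 lower by 2-fold or more. At 1.56 µg/L limma called 0 (3753 at an unadjusted p under 0.05; 766 called with array weights), and the direct comparison of the concentrations called 0 (3327 unadjusted). Run 7 fitted alone called 0 (9472 at an unadjusted p under 0.05, smallest adjusted p 0.0555). Slide as a block left 163, scan day as a block left 101, and the scan days that held most arrays called 12 and 0. Fold changes in run 7 alone are the same by construction, with a median standard error over the called probes of 0.20 against 0.18. With scan day as a block the called changes had a median size of 0.60 log2 units, and 100% kept their sign. The share of higher probes among the calls was 68.8% here and 49.1% in the authors' table, so the balance of directions depended on the scaling.

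A signature of 25 probes each way, trained on the pooled class comparison in other runs, separated exposed from control arrays past the test in run 6, and with 10 probes each way also in run 2 (AUC 0.715, exact adjusted p 0.0338). The AUC was 0.621, 0.680 and 0.631 in runs 1, 2 and 3 (exact Mann-Whitney adjusted p 0.153, 0.109 and 0.131). It was 0.381 in run 4, 0.271 in run 5, 0.926 in run 6 and 0.709 in run 7 (exact adjusted p 0.349, 0.131, 0.00319 and 0.131). All 50 probes of the signature trained on runs 1 to 3 together, which scored runs 4 to 7, were also called for bifenthrin. In runs 1, 2 and 3 the AUC of bifenthrin alone was 0.991, 0.994 and 1, that of cypermethrin 0.533, 0.507 and 0.523, that of esfenvalerate 0.369, 0.685 and 0.517, and that of permethrin 0.520, 0.500 and 0.514. In run 4 the AUC was 0.420 at 0.15 and 0.338 at 0.3 µg/L bifenthrin. Whether AUC differed between runs or compounds was not tested.

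The bifenthrin profile score placed controls as well as exposed larvae on the axis of change seen in runs 1 to 3. Bifenthrin arrays exceeded the controls of their run by 1.25 (95% interval 0.965 to 1.51), 0.768 (0.560 to 0.970) and 0.558 (0.392 to 0.735) in runs 1, 2 and 3, with exact Mann-Whitney adjusted p of 1.65e-06, 2.03e-06 and 1.65e-06. They lay above every control on 9 of 11, 9 of 10 and 8 of 11 arrays. In run 4 the difference was 0.0451 (-0.205 to 0.294) at 0.15 µg/L and -0.0694 (-0.269 to 0.146) at 0.3 µg/L. Control arrays of run 4 already scored 1.19 ± 0.210 (SD, n = 8) and those of run 5 scored 1.17 ± 0.323 (n = 7), against 0.232 ± 0.234 (n = 20), 0.143 ± 0.139 (n = 18) and -0.172 ± 0.113 (n = 20) in runs 1, 2 and 3. Run 7 controls scored 0.787 ± 0.295 (n = 10). Run 6 controls scored 0.650 ± 0.166 (n = 9), and esfenvalerate exceeded them by 0.349 (0.165 to 0.556) at 0.5 µg/L and by 0.695 (0.488 to 0.885) at 1 µg/L. The exact adjusted p was 0.0200 and 0.0364, with 5 of 9 and 3 of 3 arrays above every control. At 1 µg/L the bootstrap resampled only 3 exposed arrays, all from 1 scan day, so its interval can be much too narrow. With all 3 above every control, the unadjusted exact p was the smallest that these numbers of arrays allow. In run 7 the differences of 0.152 and 0.180 did not pass the test (exact adjusted p 0.405 for both), and neither did those of -0.294 and -0.206 in run 5 (exact adjusted p 0.272 and 0.460).

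**Figure D4:**
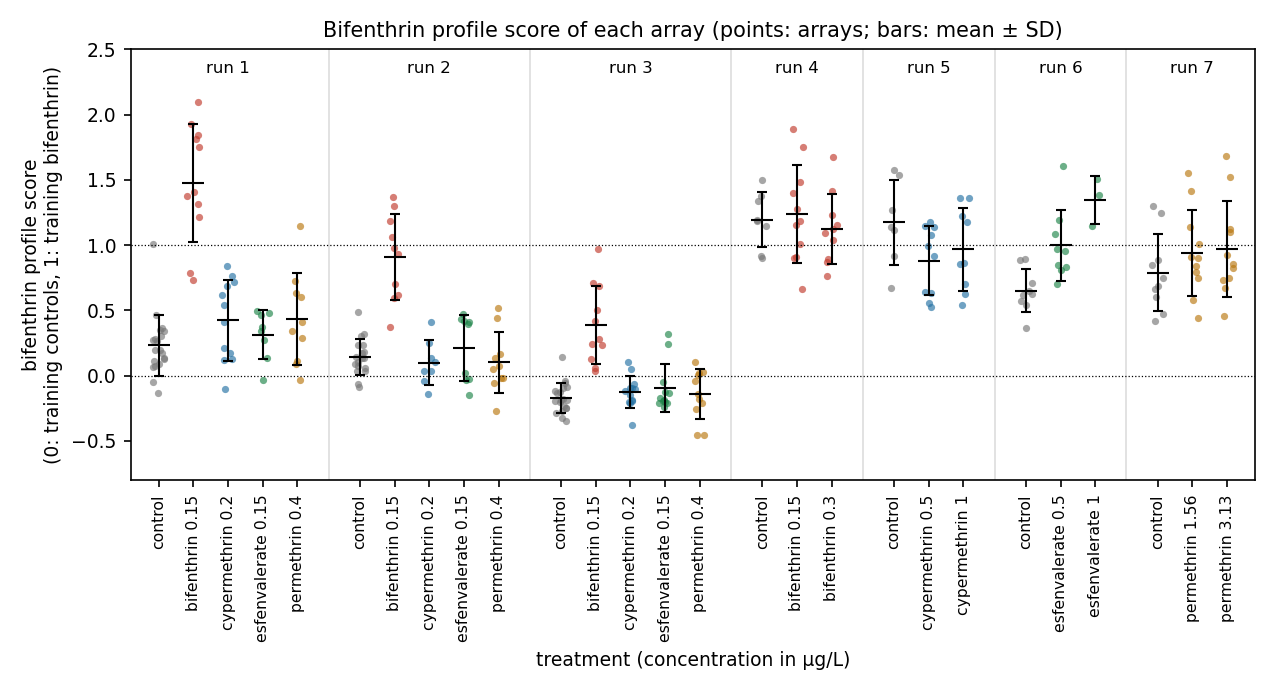
Points are arrays, with mean and SD as bars, by run and treatment (horizontal axis, concentration in µg/L), and the vertical axis is the bifenthrin profile score, unitless, where 0 is the mean of the training controls and 1 that of the training bifenthrin arrays. Controls averaged 0.232 in run 1 and 1.19 in run 4, where arrays exposed to 0.15 µg/L bifenthrin averaged 1.24.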

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

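The tests that weigh explanations below, their bounds and the counts over other splits of the arrays were chosen after the results were seen, apart from slide as a block, which was set beforehand.

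The effect of 0.15 µg/L bifenthrin differed between runs 1 to 3 and run 4, which was marked because the same contrast gave different effects in different groups of larvae. The test of the difference called 5345 of 46026 probes, 4273 of them among the 15044 called in runs 1 to 3. The effect of 0.15 µg/L in runs 1 to 3 differed from that of 0.3 µg/L in run 4 at 15471 probes, 7639 of them among those calls. Among runs 1, 2 and 3 themselves the effect of bifenthrin differed at 232 probes, 200 of them among the calls.

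Bifenthrin at 0.15 µg/L called 15044 probes in runs 1 to 3 and 0 in run 4 with limma (5169 at an unadjusted p under 0.05). With arrays taken as independent, too few arrays in run 4 were argued against for the profile as a whole, though not for single probes with small changes. The upper 95% bound of its profile score difference, 0.294, lay below the lowest lower bound of runs 1 to 3, 0.392. These intervals resampled single arrays, some of which shared an aquarium, so they can be too narrow. Too few independent aquaria in run 4 were therefore not excluded. The lowest bound came from run 3, which was scored with runs 1 and 2 as training, and run 4 with runs 1 to 3. A slide and scan batch shared by runs 4 to 7 was argued against for the part in which run 4 controls scored 0.492 above run 6 controls within slides (95% interval 0.201 to 0.783). That comparison concerns the level of the controls, not the missing difference between exposed and control arrays. Scaling to the 75th percentile was argued against because run 4 controls averaged 1.14 in the authors' quantile-normalized values. In those values exposed arrays at 0.15 µg/L differed from controls by 0.0567 (95% interval -0.189 to 0.305). Controls of all of runs 4 to 7 scored higher (1.19, 1.17, 0.650 and 0.787) than those of runs 1 to 3 (at most 0.232), and for this common rise a slide and scan batch cannot be told apart from a difference in the larvae, since no slide or scan day held arrays of both sets of runs. A difference between runs in the larvae, their condition or the RNA preparation may have left little room for the bifenthrin profile and was not tested.

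Cypermethrin in run 5 called 1244 probes at 0.5 µg/L and 3 at 1 µg/L. Noise at 1 µg/L was argued against, since the concentrations differed directly at 2414 probes, against at most 4 in the other splits. Slide was argued against, since 1545 probes were called at 0.5 µg/L with slide as a block. Exchanged labels of the concentrations cannot be told apart from a larger response at 0.5 µg/L, because the 1244 calls rest on the labels and no value in the files gives the concentration independently. A response that is larger at the lower concentration stayed open and was not tested.

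Permethrin at 3.13 µg/L called 1845 probes in the fit of runs 4 to 7 and 0 in run 7 alone. Both fits compare exposed arrays with the controls of run 7, so the fold changes are the same by construction. Over the called probes the median standard error was 0.18 in the joint fit and 0.20 in run 7 alone. All 1839 of them tested in run 7 alone had an unadjusted limma p under 0.05 there, and the smallest adjusted p was 0.0555. The probes were picked on the same arrays and fold changes, so their unadjusted p was nearly fixed in advance and is no further evidence. Scan day was argued against only as the main source of the fold changes. With scan day as a block the median size of the called changes went from 0.64 to 0.60 log2 units, and 100% kept their sign. The fall was less than their median standard error of 0.18, the bound chosen after the results were seen. That error does not measure how far a block moves an estimate from the same arrays. The probes were also picked for their changes without the block, so kept signs were likely in advance. The number of calls did depend on scan day. It went to 101 with the block, and to 12 and 0 within the scan days that held most arrays, where fewer arrays enter the fit. Run 7 as a whole was not noisier over all probes, with a median ratio of its spread to that of runs 4 to 7 of 0.999. Over the called probes the ratio was 1.11, which cannot be told apart from the choice of probes, since calling a probe in the fit of 4 runs favours a small spread in the others. The groups of run 7 differed in spread, with 0.33 in controls, 0.35 at 1.56 and 0.51 at 3.13 µg/L, the highest of the groups of runs 4 to 7. Replicates 3, 7 and 8 at 3.13 µg/L had median correlations with their group of 0.924, 0.901 and 0.933, and replicate 6 of the controls had 0.937. A fit without these arrays was not run. A response to permethrin stayed open, and a difference between the 2 concentrations was called at 0 probes with limma (3327 at an unadjusted p under 0.05).

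Treatments were reassigned among the arrays of each run in 100 splits, the real one included, and each was fitted in full. The real grouping was the only 1 of the 100 with as many calls for the class comparison (3050, highest other 3), bifenthrin in runs 1 to 3 (15044, highest other 2729), the alpha-cyano contrast (5619, highest other 4) and any difference among the compounds (10475, highest other 2). The same held for bifenthrin against cypermethrin (11637, highest other 331), against esfenvalerate (10176, highest other 1) and against permethrin (10817, highest other 259). In runs 4 to 7 it held for 0.3 µg/L bifenthrin (12236, highest other 1198), its difference from 0.15 µg/L (9322, highest other 11), 0.5 µg/L cypermethrin (1244, highest other 5), its difference from 1 µg/L (2414, highest other 4) and 3.13 µg/L permethrin (1845, highest other 7). For these counts a chance assignment of single arrays was excluded at a share under 0.05, but the splits could not keep arrays of the same aquarium together. Each split of runs 1 to 3 also scattered the bifenthrin arrays, whose response enters every comparison of these runs listed here. The splits therefore do not test a class or alpha-cyano effect apart from bifenthrin. For 1 µg/L cypermethrin 4 of the 100 splits gave as many as the real 3 calls (highest other 8), and the count fell to 0 under 5 of its alternatives.

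For 1 µg/L esfenvalerate 23 of 100 splits gave as many as the real 8 calls (highest other 2016), and for its difference from 0.5 µg/L 48 of 100 gave as many as the real 1 (highest other 1736), so chance was not excluded for either. Where the real count was 0 with limma, 100 of 100 splits had to give as many, so the splits test nothing there and only the highest others are given. The highest others were 22 for cypermethrin, 6566 for esfenvalerate and 409 for permethrin in runs 1 to 3, whose unadjusted counts were 1320, 1119 and 1688. They were 3 for cypermethrin against esfenvalerate, 2 for cypermethrin against permethrin and 208 for esfenvalerate against permethrin, with 813, 982 and 1209 unadjusted. In runs 4 to 7 they were 1144 for 0.15 µg/L bifenthrin, 102 for 0.5 µg/L esfenvalerate, 9 for 1.56 µg/L permethrin and 2 for the difference of the permethrin concentrations. Some splits called far more probes than the real grouping, as for esfenvalerate and for 0.15 µg/L bifenthrin. Such splits also move arrays of the other treatments of a run into the compared groups, and the source of their calls was not tested.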

How the results depend on the processing

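Scan day as a block, the removal of arrays and the class mean without bifenthrin were chosen after the results were seen, and the cause of the changes below was not tested. For bifenthrin against control in runs 1 to 3, each of the 4 named probes kept its direction and passed the test under all 15 alternatives, with log2 fold changes from 1.77 to 2.28, 1.76 to 2.28, -1.65 to -1.13 and -2.38 to -1.52 and a highest adjusted p of 0.000370. The counts for 0.3 µg/L bifenthrin and its difference from 0.15 µg/L stayed within 1.5 times under all 13 alternatives, and that of bifenthrin minus permethrin under all 17. Comparisons that called 0 with limma stayed at 0 under all 17 alternatives for the other pairs of compounds, and under all 13 for 0.5 µg/L esfenvalerate and for the difference between the 2 permethrin concentrations. Within the scan days that held most arrays, a further fit, 0.5 µg/L esfenvalerate called 1 and 21. Without the 3 arrays that stood apart, bifenthrin in runs 1 to 3 called 15939 and the class comparison 3586. Signal over background limits dim probes: the lowest array had 37.9% of spots well above it. Alternatives that need gene names (1 probe per gene, gene lists) were not run. Replicate numbers did not pair arrays across groups (mean r 0.0242 over 394 same-number pairs), so the replicate block has no pairing to use.

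For 1 µg/L cypermethrin (3 calls) the count was 0 with normexp, with the authors' table, with the 90% filter, with slide fixed and with run 5 alone, 7 with slide random, 9 with array weights and 8 with the replicate block. For 1.56 µg/L permethrin (0) it was 28 with normexp, 29 with the authors' table, 766 with array weights and 1 with run 7 alone. For 3.13 µg/L permethrin (1845) it was 2841 with quantile normalization, 163 with slide fixed, 476 with slide position, 3596 with array weights, 0 with run 7 alone and 101 with scan day. For 0.15 µg/L bifenthrin in run 4 (0) it was 24 with quantile normalization, 4 with slide fixed, 4 with slide random, 5 with slide position and 18 with the replicate block. For 1 µg/L esfenvalerate (8) it was 17 with quantile normalization, 5 with array weights, 0 with the replicate block, 0 with run 6 alone and from 0 to 14 with a replicate left out. Its difference from 0.5 µg/L (1) gave 4 with quantile normalization, 2 with slide position, 16 with array weights and 0 with the 90% filter, the replicate block or run 6 alone. Array weights gave 2985 for 0.5 µg/L cypermethrin (1244) and 5301 for the difference of its concentrations (2414).

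In runs 1 to 3 the class comparison (3050) gave 4821 with array weights, 1893 with the replicate block, 1 with run as the unit, 0 without bifenthrin, and from 701 to 2520 with a run left out. With run as the unit bifenthrin (15044) gave 8883, the alpha-cyano contrast (5619) 2299 and any difference (10475) 5959. With a run left out these gave 9167 to 13687, 2326 to 4573 and 6946 to 8327, bifenthrin minus cypermethrin (11637) 7505 to 9064, and bifenthrin minus esfenvalerate (10176) 6601 to 8593; fewer arrays enter these fits. Cypermethrin and esfenvalerate gave 0 to 2 and permethrin 0 to 1 with a run left out, and esfenvalerate 1 with array weights. The signature AUC of run 2 rose from 0.680 to 0.715 with 10 probes each way and then passed the exact test; the other runs stayed on the same side.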

Other observations

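The tests in this part were all chosen after the results were seen.

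Whether the fold changes of cypermethrin, esfenvalerate and permethrin in runs 1 to 3 followed those of bifenthrin stayed undecided. Across probes r with bifenthrin was 0.29, 0.40 and 0.38, but the exposures share controls, and treatments reshuffled within runs gave a median r of 0.38, 0.33 and 0.45, with 67, 38 and 69 of 100 as high. With the controls split so that no array was shared, r was 0.19 and 0.16 for cypermethrin, 0.33 and 0.21 for esfenvalerate, and 0.26 and 0.20 for permethrin. Reshuffled treatments gave as high a covariance with bifenthrin in 10, 4 and 6 of 100 cases. The reshufflings moved the bifenthrin arrays as well, so the bifenthrin response did not stay in place. They therefore cannot decide whether the other compounds followed bifenthrin, and the r with split controls had no reference. Between different runs r was mixed in sign, from -0.11 (permethrin in run 2, bifenthrin in run 3) to 0.27 (cypermethrin in run 1, bifenthrin in run 2).

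A signature trained without bifenthrin was scored in runs 1, 2 and 3 on the 30, 27 and 36 arrays of the other pyrethroids. It had an AUC of 0.402, 0.397 and 0.399, none of which differed from 0.5 past the test (exact Mann-Whitney adjusted p 0.356 for each). In runs 4 to 7 it had 0.649, 0.361, 0.898 and 0.527, and only run 6 passed the exact Mann-Whitney test (adjusted p 0.00915). Since the class mean without bifenthrin had no called probe in runs 1 to 3, the run 6 value does not show a class signature.

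The median spread between arrays of a group, as an SD on the log2 scale over all probes, was 0.51 with 3.13 µg/L permethrin and 0.33 in the controls of the same run. No 2 arrays were copies of each other, with a highest correlation of any pair of 0.987 over 48247 probes.

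A hypothesis of a response common to 0.3 µg/L bifenthrin in run 4 and 0.5 µg/L cypermethrin in run 5 was tested. Their fold changes correlated with r of 0.51 across 43441 probes, and 0.57 with slide as a block, while 100 reshufflings of treatments within runs gave at most 0.35. Of the probes called for both, 245 rose in both (46.0 for independent calls) and 680 fell in both (140), with 0 in opposite directions. Within scan days r was 0.32, with 1 of 100 reshufflings within run and day as high, and 0.11, with 23 of 100 as high. A common response may exist, but the test left it undecided, since 1 of the scan days did not separate it from reshuffled arrays. That day held 2 controls of run 5 and 4 of run 4, and the other day held 2 arrays at 0.5 µg/L cypermethrin, so both r rest on few arrays.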
